A study of Homo sapiens with 6 samples.

How the data were processed

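Total RNA from TF-1 cells carrying a control vector (3 arrays) or human PRL-3 (3 arrays) was measured on a whole-transcript human expression array. Per the labels, the cells grew in RPMI with fetal bovine serum and interleukin-3, RNA was taken with a Qiagen RNeasy kit, and biotin-labelled cDNA was made with Nugen Applause and Encore kits. The deposited table held 1 intensity per probe set and array, for 28869 probe sets. The values were positive, on a linear scale, and their medians lay close together, so they were taken as already normalized, which no source used here states. How the authors summarised the probes, corrected the background and normalized the arrays was not given in the sources used here. A between-array step, if there was one, can remove a change shared by most genes, so all differences are relative to the bulk of the genes.

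The log2 of each deposited intensity was taken, with no offset and no further normalization. Probe sets were named through the platform annotation: 19310 had exactly 1 gene symbol, 1752 had several and 7807 were not named here. Of the first, 19279 matched a current gene by Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. Genes were tested on probe sets with exactly 1 symbol, and of the 685 genes with more than 1 probe set the brightest over all 6 arrays stood for the gene, which left 18377 genes. In 0 of these 685 genes did probe sets pass the test in opposite directions, and in 50 some passed and others did not. The table gave no detection call, so no gene was left out as undetected and low intensities have no known floor.

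PRL-3 and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, not robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given after a difference are limma's moderated standard errors, and errors given after a level are SD over 3 arrays. Gene lists with at least 5 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry, all adjusted over 29 lists. Camera compares the test statistics of a list with those of all other genes, so its direction is relative to them. The 30 lists, the groups, the tests and the rule for naming genes were fixed before the data were examined. The rule named PTP4A1, PTP4A2, PTP4A3, LIN28B, LEO1 and STAT3 whatever their result. It then named the 12 largest rises and the 12 largest falls past the threshold among genes whose higher group lay above the median level of all genes and whose groups did not overlap, leaving out uncharacterised loci, small RNA genes, olfactory receptors and sex-linked marker genes. Of each list it named up to 4 members with the largest differences past the threshold.

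Nothing in the labels says that the 3 arrays of a group came from separate cultures or separate transfections, so p-values measure only the spread between these arrays, which may be technical. The labels gave no batch or date. The number of arrays limits the precision. The test was tried on simulated data for this comparison, with 200 of 18377 genes changed: it recovered 58.2% of genes changed by 0.5, 88.1% of those changed by 1 and 97% of those changed by 2 on the log2 scale, with 4 false calls among 166. With no gene changed it made 0 calls. The simulated spread was drawn independently for each gene and array, whereas in the real arrays 1 direction held 0.639 of the within-group variance. These rates may therefore not hold for the real comparison.

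The alternatives tried were quantile normalization, a shift of each array to 1 median, an intensity trend with robust variances, array weights, 2 filters on dim genes, the mean of a gene's probe sets, all probe sets, an unequal-variance test, a minimum size of 2-fold, and leaving out each array in turn. A fit with the main direction of the within-group spread as a covariate and a fit without control 1 and PRL-3 5 were added after the data had been seen. Members of the lists that lie on probe sets with several symbols, among them the alpha and gamma globins and the classical HLA class I genes, were not analysed here. Figures were drawn with matplotlib in Python; genes were ordered along chromosomes by the RefSeq table only to find neighbours.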

Results

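The data compared TF-1, a human erythroleukaemia line that needs a cytokine to grow, after transfection with a control vector or with human PRL-3, the protein tyrosine phosphatase encoded by PTP4A3. The stated purpose of the series was the part of PRL-3 in leukaemia. Each group had 3 arrays, numbered 1 to 3 for control and 4 to 6 for PRL-3. Median intensity per array ran from 89.8 to 92.9. Across genes, log2 values of array pairs correlated at r = 0.9861 to 0.9964 within groups and 0.9774 to 0.9863 between groups. These values are a description, since genes are not independent replicates. The 2 ranges overlapped: control 1 correlated at 0.9863 with PRL-3 5 and at 0.9861 with control 3. The first principal component held 50.5% of the variance and separated the groups. The second held 31.4% and lay within the groups, with control 1 and PRL-3 5 towards one end and control 3 at the other.

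**Figure D1:**
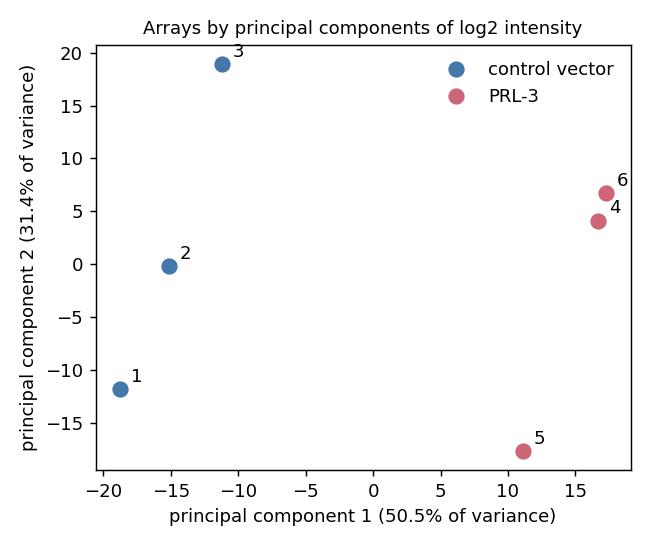
Each point is 1 array of TF-1 cells, labelled with its replicate number, on the first (50.5% of variance) and second (31.4%) principal components of log2 intensity. The 3 PRL-3 arrays lie to the right of the 3 control arrays, and the second axis spreads arrays of both groups.

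PTP4A3 was the gene with the largest rise. Its probe set (8148501) read 7.97 ± 0.056 in control and 10.84 ± 0.076 in PRL-3 arrays (log2 intensity, SD, n = 3 each). The difference of 2.87 ± 0.072 (log2, SE) was 7.33-fold, with adjusted p = 2.24e-06 by limma. An exact two-sided permutation test of the same 6 values gave p = 0.1, the smallest that 3 against 3 can give. The closest relatives did not pass: PTP4A1 differed by 0.08 ± 0.1 (adjusted p = 0.732) and PTP4A2 by -0.17 ± 0.076 (adjusted p = 0.276, limma). PTP4A1 changed sign, to -0.018, without PRL-3 6.

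The metallothioneins MT2A, MT1G and MT1X, small proteins that bind zinc and copper, rose by 2.37, 2.37 and 2.32 on the log2 scale (5.18-, 5.17- and 5.01-fold). The other probe sets annotated to MT2A rose by 1.83 and 1.77. Their numbers lie between those of KIT and CXCL8 and far from that of the main one. They may not lie on MT2A itself, so they are not a separate check of its rise. LIN28B, which blocks maturation of let-7 microRNAs, rose by 2.09 ± 0.118 (4.25-fold, adjusted p = 9.37e-05, limma), from a control level at the 12.5 percentile of all genes. HBB, adult beta globin, dropped by 2.15 on the log2 scale and was 4.45-fold lower with PRL-3 (adjusted p = 3.24e-06, limma). In all, 1413 of 18377 genes passed adjusted p 0.05 in limma, 842 higher and 571 lower with PRL-3. Of these, 67 were at least 2-fold higher and 19 at least 2-fold lower. The groups did not overlap in 24.3% of genes, where chance gives 10% on average over labellings. Genes are not independent, so a single labelling can lie far from this average.

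The other large rises were NTS, the precursor of neurotensin (1.97), CALB1, a calcium-binding protein (1.93), SHOC2, a scaffold of RAS to RAF signalling (1.92), CRYAB, a small heat shock protein (1.90), the histone gene H2BC12 (1.78), MSRA, which repairs oxidised methionine (1.72), and the tight junction gene TJP1 (1.72). The other large falls were COL14A1, a collagen (-1.78), CD36, a scavenger receptor (-1.53), HGSNAT, a lysosomal enzyme (-1.27), the sodium channel gene SCN9A (-1.25), CD38, an enzyme that breaks down NAD (-1.23), NCOA5 (-1.21), VSTM1 (-1.18), ALAS2, the first enzyme of haem synthesis in red cells (-1.17), RYR3 (-1.15), the chemokine receptor gene CCR4 (-1.15) and the kinase gene TXK (-1.11). All values are log2 differences, PRL-3 minus control, and adjusted p in limma ran from 1.2e-05 for MSRA to 0.0031 for HGSNAT. LEO1 (0.28, adjusted p = 0.525) and STAT3 (-0.22, adjusted p = 0.231), both linked to PRL-3 in published work, did not pass. With 1 array left out LEO1 ranged from 0.092 (without control 1) to 0.454 (without PRL-3 5). STAT3 ranged from -0.306 to -0.168, and neither passed in these fits. STAT3 passed with array weights (-0.31, adjusted p = 0.00627), and with the main direction of the within-group spread as a covariate, a fit added after the data were seen, STAT3 (adjusted p = 0.0233) and LEO1 (adjusted p = 0.0143) passed; both settings take their terms from the spread of these same arrays.

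**Figure D2:**
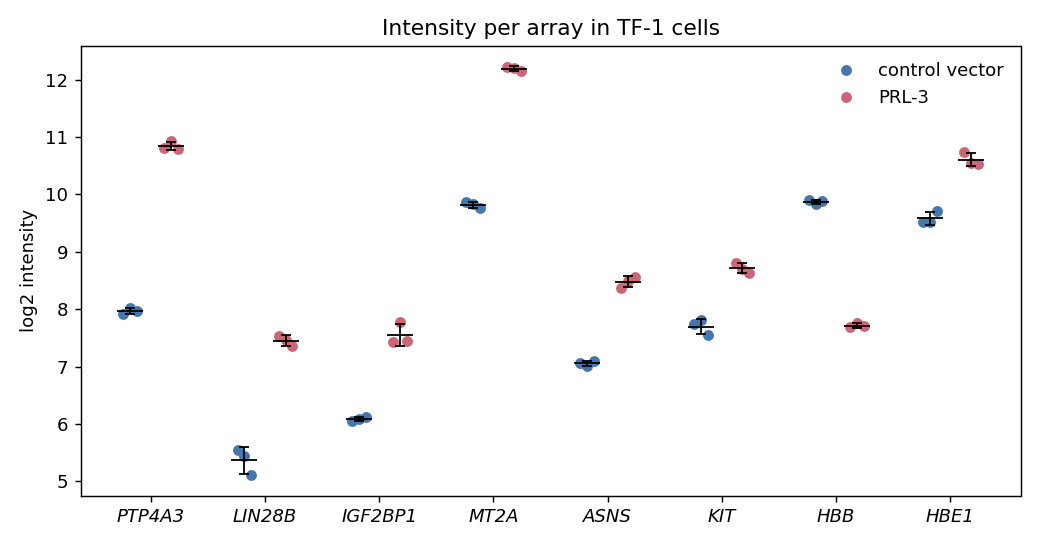
Log2 intensity of 8 genes in each array, with control vector arrays in blue and PRL-3 arrays in red; lines give the mean and bars the SD of 3 arrays. PTP4A3 lies near 7.97 in control and 10.84 in PRL-3 arrays, and HBB is the gene shown that is lower with PRL-3.

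The counts of genes depended on the test and on single arrays. An unequal-variance test of each gene, which does not share the spread across genes, called 7 genes higher and 4 lower, with PTP4A3, MT2A and HBB among them but not LIN28B (adjusted p = 0.121), and without control 2 limma called 388 higher and 178 lower.

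Of 29 gene lists tested, 13 passed camera with its preset correlation, 10 higher and 3 lower with PRL-3. None of the 29 passed camera with an estimated correlation, where 7 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, called 10. These left out 6 of the 13, with fry's adjusted p at 0.0513 for antigen presentation, 0.0513 for immediate early genes, 0.0943 for glycolysis, 0.153 for histones, 0.155 for ribosomal proteins and 0.264 for JAK-STAT feedback, and took in p53 targets, LIN28 and let-7, and cytokine receptors. Without control 3 the lists for glycolysis, cholesterol synthesis, histones, ribosomal proteins and JAK-STAT feedback no longer passed while that for the PAF1 complex did, which made 9. Without PRL-3 5 the lists for cholesterol synthesis, histones, ribosomal proteins and JAK-STAT feedback were lost, which left 9. Without control 1 the lists for LIN28 and let-7 (adjusted p = 0.048), cytokine receptors (0.0485) and the interferon response (0.0485) passed too, which made 16, and without PRL-3 6 the LIN28 list did (0.0251), which made 14.

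The integrated stress and unfolded protein response list was higher with PRL-3 in camera (adjusted p = 6.23e-09), with adjusted p = 0.0931 with an estimated correlation. Of its 31 members 9 rose, 0 fell and 22 did not pass, and 11 rose when adjusted over the list alone. The largest were ASNS and PSAT1, which make asparagine and serine (1.42 and 0.93), the mTORC1 inhibitor gene DDIT4 (0.76) and VLDLR (0.69). Glycolysis and hypoxia genes followed, with 7 of 30 higher and 0 lower, and the same 7 and 0 in number adjusted over the list alone. They included the glucose transporter gene SLC2A3 (1.36), ENO2 (1.33), ALDOC (0.65) and NDRG1 (0.63). The list had adjusted p = 0.0013 in camera and adjusted p = 0.405 with an estimated correlation. Subunits of oxidative phosphorylation were higher in 4 of 29 and lower in 0, and 8 and 0 adjusted over the list alone, with COX6C (0.52) and NDUFB3 (0.37) largest. Their adjusted p was 3.2e-06 in camera, and adjusted p = 0.0931 with an estimated correlation. In cholesterol and fatty acid synthesis 5 of 27 rose and 0 fell, and 6 and 0 adjusted over the list alone. They were led by MSMO1 (1.34), STARD4 (0.69), INSIG1 (0.66) and SQLE (0.55), with adjusted p = 0.016 in camera and adjusted p = 0.181 with an estimated correlation.

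The erythroid list was lower with PRL-3 in camera (adjusted p = 8.41e-08), with adjusted p = 0.181 with an estimated correlation. Of its 30 members 12 fell, 2 rose and 16 did not pass, and 15 fell and 2 rose adjusted over the list alone. HBB, ALAS2 and HBD, the delta globin gene (-1.07), fell, while HBE1, the embryonic epsilon globin gene, rose by 1.02 ± 0.09 (log2, SE, adjusted p = 0.000732, limma). CA2, a carbonic anhydrase, was the other member that rose (0.90); it was named after its value was seen. HBB and HBD are near-identical, so each may read part of the other. Mast cell, basophil and eosinophil genes were higher in 6 of 22 and lower in 1, and in 8 and 1 adjusted over the list alone. The largest were PRG2, the major basic protein of eosinophil granules (1.52), KIT, the stem cell factor receptor (1.02), and IL5RA (0.87). Adjusted p was 0.0013 in camera, and adjusted p = 0.0981 with an estimated correlation.

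**Figure D3:**
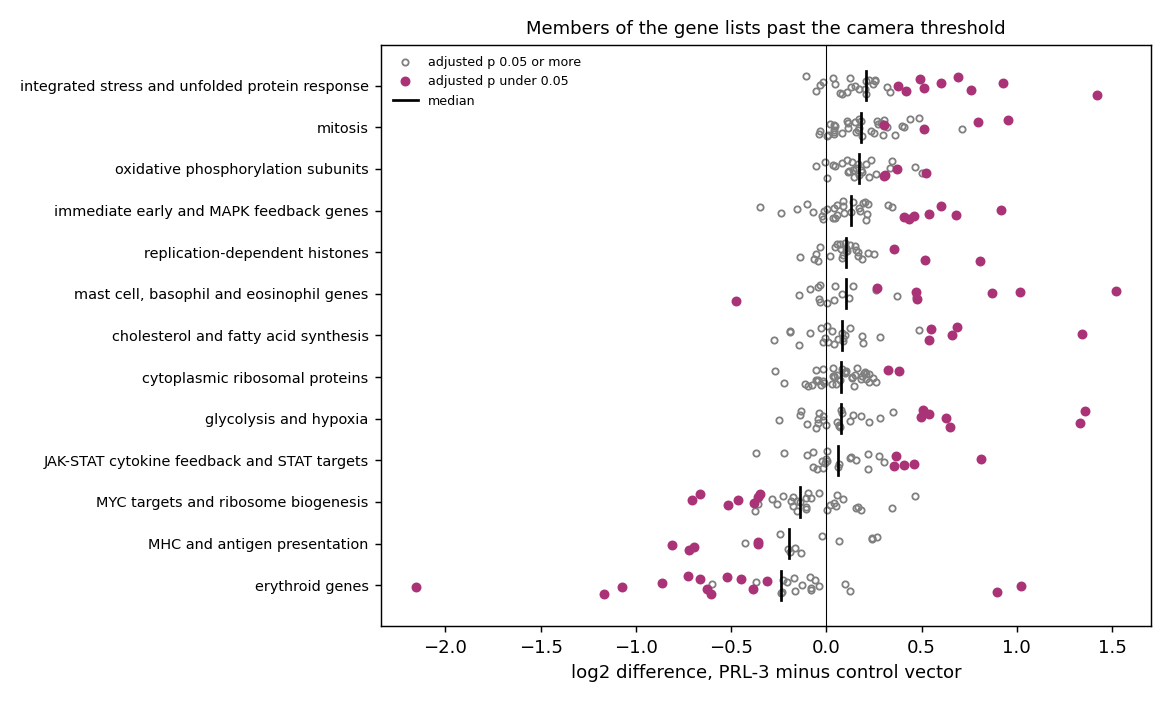
Log2 differences, PRL-3 minus control vector, of the members of the 13 gene lists past the camera threshold; filled points passed limma at adjusted p 0.05, open points did not, and black bars are list medians. Erythroid genes include HBB at -2.15 on the left and 2 genes near 1 on the right.

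Mitosis genes were higher with PRL-3 in 4 of 39 and lower in 0, and in 12 and 0 adjusted over the list alone. They were PTTG1 (0.95), NEK2 (0.80), CDK1 (0.51) and KIF20A (0.30), with adjusted p = 5.57e-08 in camera and adjusted p = 0.0981 with an estimated correlation. In S phase and DNA replication 0 of 39 passed, also when adjusted over the list alone, and 12 had an unadjusted p under 0.05 in limma; the list had adjusted p = 0.351. MYC targets and ribosome biogenesis genes fell in 7 of 35 and rose in 0, and were 7 lower and 1 higher adjusted over the list alone. The falls included the RNA polymerase I subunits POLR1B (-0.70) and POLR1A (-0.46), UTP20 (-0.66) and NIP7 (-0.52). The list had adjusted p = 0.00238 in camera and adjusted p = 0.0981 with an estimated correlation. For ribosomal proteins camera's test pointed up, at a mean difference of 0.078. RPS24 (0.38) and RPS29 (0.33) were the 2 of 42 that rose and 0 fell, with 1 and 0 adjusted over the list alone. These 2 of 42 are close to the share among all genes, where 842 of 18377 were higher. The ribosomal protein list had adjusted p = 0.01 in camera, adjusted p = 0.396 with an estimated correlation, and 0.149 in camera after quantile normalization. Histone genes rose in 3 of 27 and fell in 0, with equal counts adjusted over the list alone, namely H1-2 (0.81), H1-3 (0.52) and H3C3 (0.35). The histone gene H2BC12, with a rise of 1.78, is not a member of the list. That list had adjusted p = 0.00546 in camera and adjusted p = 0.396 with an estimated correlation.

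Immediate early and MAPK feedback genes rose in 7 of 35 and fell in 0, and were 8 higher and 1 lower adjusted over the list alone. JUN (0.92), ETV4 (0.68), NR4A2 (0.60) and ETV5 (0.54) were the largest. The list had adjusted p = 0.000112 in camera, adjusted p = 0.396 with an estimated correlation, and 0.493 among genes above the median level. JAK-STAT feedback genes rose in 5 of 26 and fell in 0, and were 6 higher and 1 lower adjusted over the list alone. They were led by PIM1 (0.81) and DUSP6 (0.46), and 6 members stood in the immediate early list too. Adjusted p was 0.0124 in camera, and adjusted p = 0.578 with an estimated correlation. Antigen presentation genes fell in 5 of 16 and rose in 0, and were 8 lower and 1 higher adjusted over the list alone. HLA-DPB1 (-0.81), HLA-DMA (-0.72) and HLA-DPA1 (-0.69) fell most; these class II genes have close copies and haplotype probe sets, so single values are uncertain. The list had adjusted p = 0.00649 in camera and adjusted p = 0.383 with an estimated correlation.

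The other 16 lists did not pass camera. Some were chosen from published work on PRL-3, which may include these samples, so they are not independent evidence: those for LIN28 and let-7, the PAF1 complex, PI3K and mTOR, adhesion, and JAK-STAT feedback above. In the LIN28 list 3 of 16 rose and 0 fell, also adjusted over the list alone, namely LIN28B, IGF2BP1, a let-7 target gene (1.46), and MYCN (0.56). Its adjusted p was 0.109, and its mean was 0.24 while its median was -0.039. In the PAF1 complex list 0 of 20 rose and 1 fell, SUPT4H1 (-0.28), with 0 adjusted over the list alone and adjusted p = 0.0718; it passed after quantile normalization, at 0.0271. In the PI3K list 1 of 25 fell, TSC2 (-0.39), and 0 rose, alike adjusted over the list alone, with adjusted p = 0.76; its test pointed up, its mean was -0.006 and its median 0.059. Adhesion, migration and matrix genes rose in 4 of 44, with CDH2, the N-cadherin gene, at 1.27, and fell in 1, with 5 and 5 adjusted over the list alone and adjusted p = 0.25.

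Among lists of cell identity, cytokine receptors and their kinases rose in 5 of 22 and fell in 0, with 6 and 2 adjusted over the list alone and adjusted p = 0.121, and included FYN (1.15) and IL6ST (0.61). Stem and progenitor genes rose in 4 of 30 and fell in 3, with 6 and 4 adjusted over the list alone and adjusted p = 0.82; MEIS1 rose by 0.62 and ERG dropped by 0.92. Megakaryocyte genes rose in 4 of 23 and fell in 2, with 5 and 6 adjusted over the list alone and adjusted p = 0.76, and LTBP1 (0.96) was largest. Granulocyte and monocyte genes rose in 3 of 30 and fell in 3, with 4 and 3 adjusted over the list alone and adjusted p = 0.984; CD68 differed by 0.91 and CYBB by -0.55. In these last 3 lists the mean was above 0 (0.023, 0.048 and 0.0097) and the median below it (-0.013, -0.028 and -0.024), and the test pointed up in the first 2 and down in the third. As markers of cells that should be absent, lymphocyte genes rose in 1 of 26 (PRF1, 0.50) and fell in 0, alike adjusted over the list alone, with adjusted p = 0.491. Fibroblast, epithelial and endothelial genes rose in 1 of 22 (KDR, 0.59) and fell in 0. Adjusted over the list alone the counts were 2 and 1, and the list had adjusted p = 0.82 in camera. KDR lay at the 89.8 percentile of all genes in control arrays, so here it does not mark absent cells.

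Among lists of stress and death, p53 targets rose in 4 of 25 and fell in 0, also adjusted over the list alone, with FAS (0.91) and PMAIP1 (0.71) largest. Their adjusted p was 0.16, with a mean of 0.11 and a median of -0.022. BCL2 family genes rose in 3 of 24 and fell in 0, with 3 and 1 adjusted over the list alone and adjusted p = 0.254, and included APAF1 (0.52). Heat shock genes rose in 1 of 15 (CRYAB) and fell in 0, alike adjusted over the list alone, with adjusted p = 0.25. Interferon response genes rose in 4 of 33 and fell in 4, with 4 and 5 adjusted over the list alone and adjusted p = 0.127; IFIT1 rose by 0.80 and XAF1 dropped by 0.70. Inflammatory genes rose in 2 of 28 and fell in 1, alike adjusted over the list alone, with adjusted p = 0.449; CCL5 (1.03) and CXCL8 (0.51) rose and NFKB1 dropped by 0.61. The remaining list, the PTP4A family, had too few members for the test. Of the list members given above, PTTG1, KIF20A, CCL5, CXCL8, PIM1, ETV5, COX6C, NDUFB3, RPS24, RPS29, H1-3, H3C3, STARD4, INSIG1, NDRG1, POLR1A, SUPT4H1, TSC2, KDR, PMAIP1 and the HLA genes lost their call in limma when at least 1 of the single arrays was left out, with adjusted p of up to 0.182, for RPS29. SUPT4H1 and KIF20A lost it whichever array was left out, with lowest adjusted p of 0.0708 and 0.069 in limma. H3C3 and RPS29 lost it in 5 of these fits.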

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

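The probe sets that the report's comparison did not use also held differences between the groups. Among 1752 probe sets with several gene symbols, 61 were higher and 58 lower with PRL-3 in limma at adjusted p 0.05. Among 7807 probe sets with no gene symbol here, 70 were higher and 56 lower. No explanation was tested for these, and no gene is named from them.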

How the results depend on the processing

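PTP4A3 stayed past the threshold in every alternative, at 2.80 to 2.90. No gene called by limma on all 6 arrays turned sign in any alternative. The counts moved: array weights gave 2122 higher and 2303 lower, and the main direction of the within-group spread as a covariate, added after seeing the data, gave 1976 and 1805. Both were tuned on the spread of these arrays, so their larger counts are not better evidence. The unequal-variance test gave 7 and 4 (2663 genes at an unadjusted p under 0.05), since each gene then rests on its own 6 values, and the 2-fold minimum gave 67 and 19. Leaving out 1 array gave 388 (without control 2) to 792 higher and 178 (without control 2) to 747 (without control 3) lower, with fewer samples. Without control 1 and PRL-3 5, also added after seeing the data, 757 and 409 passed, and 13 lists. With an estimated correlation 0 lists passed; leaving out 1 array left 9 to 16. Array weights left 10, without glycolysis (adjusted p = 0.0551), cholesterol (0.0543), histones (0.0543) and JAK-STAT (0.189) but with the PAF1 complex (0.0202). Above the median level 9 were left, without histones (0.062), ribosomal proteins (0.0614), immediate early genes (0.493) and JAK-STAT (0.493), and above the lower quartile 12, without JAK-STAT (0.129). The mean correlation between arrays of a group, 0.992, was 0.982 above the median level and 0.987 above the lower quartile. These filters leave a narrower range of levels, and whether this lowered the correlation was not tested.

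For some lists that did not pass, the direction of camera's test turned, mostly with no change in the sign of the mean difference. Since camera compares a list with all other genes, its direction need not match that sign. What turned each list was not tested. For granulocyte genes, whose test pointed down at a mean of 0.0097, it pointed up at a mean of 0.012 after quantile normalization, 0.033 with array weights and 0.031 above the median level. Tests that had pointed up pointed down with array weights, at means of 0.001 for stem cell, 0.014 for megakaryocyte and -0.062 for PI3K genes, and above the median level, at -0.11 for megakaryocyte, 0.01 for fibroblast and -0.019 for PI3K genes. Of these means only that of megakaryocyte genes above the median level had changed sign. With 1 array left out the means ranged over -0.009 to 0.054 for stem cell, 0.02 to 0.078 for megakaryocyte, -0.013 to 0.035 for granulocyte, -0.003 to 0.019 for fibroblast and -0.063 to 0.038 for PI3K genes, and the difference of PTP4A1 over -0.018 to 0.137. No paired analysis was possible because the groups share no replicate numbers. The table gives no background, so what dimness limits is unknown; 229 of the calls were dim in both groups.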

Other observations

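The family scan, the search along chromosomes, the within-group direction and all their tests in this part were chosen after the data were seen; of the counts over other splits of the samples, only the one for lists was written before its result.

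Metallothioneins rose as a family. In a scan of 340 families of like-named genes, 10 of 15 metallothionein genes were higher with PRL-3 and 0 lower, and against chance among families in both directions the adjusted p was 6.41e-08 over 680 hypergeometric tests. MT2A, MT1G and MT1X rose by 2.37, 2.37 and 2.32 (log2, brightest probe set). The other probe sets annotated to MT2A, which may not lie on that gene, rose by 1.83 and 1.77. MT1H, MT1F and MT1E rose by 0.70, 0.70 and 0.57 (log2), while MT3 and MT4, at -0.067 and 0.0068, did not pass. Many metallothionein genes are neighbours with near-identical sequences, and a probe set may read more than 1 copy. Some of the 15 carry pseudogene names: MT1DP (0.56) and MT1P3 (0.58) were among those that rose, while MT1IP and MT1JP did not pass. So the 15 are not independent values, which the hypergeometric test takes them to be.

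Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many genes: 1413 (842 and 571), where the highest other split gave 0. For gene lists past camera also 1 split gave as many, but the real 13 stood against 12 in the highest other. A total of 10 splits is too few for a share under 0.05. Every other split mixed control and PRL-3 arrays on both sides, so a difference between the real groups widened its within-group spread. The 0 is therefore no measure of noise alone.

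Most of the spread within groups lay along 1 direction, which held 0.639 of the within-group variance. After quantile normalization it still held 0.626, which argues against a plain difference of array scale. Yet the spread of intensities within arrays followed this direction. Lower and upper quartiles were 45 and 201.7 in control 1 and 45.4 and 201.2 in PRL-3 5, at one end. They were 48.2 and 189.6 in control 3, at the other end, with the remaining arrays between. Quantile normalization makes arrays alike only in their distribution, so it cannot exclude other technical causes tied to this spread. Small nucleolar and Cajal body RNAs, 192 of the 18377 genes, carried 3.16% of the direction's variance, so they did not make up most of it. So few genes could hardly carry most of it in any case, so this cannot exclude unequal capture of these RNAs. Regional sequence composition stays open as a candidate explanation: adjacent genes had like scores, with a rank correlation of 0.223 against at most 0.0347 in 1000 shuffled gene orders, but any cause shared by neighbours would give this, and no sequence was used here. With the regression on this direction taken out, at least 93% of the mean difference of each of the 13 called lists was left. This cannot settle whether the direction accounts for them. The direction was taken from the spread within groups, so its mean position is the same in both groups by construction. Any offset between groups along it was only estimated by a regression across genes, where differences and scores correlated at 0.09. The design gives no group for this direction, and no biological explanation was tested.

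Some runs of neighbouring genes had a high median difference with PRL-3, though not every member was above 0. Windows of 11, 21 and 31 genes were tried on 9160 genes above the median level, and 21 was kept after all of these had been seen; it gave 7 runs, 6 higher and 1 lower. The runs from TAF5 to NANOS1, with 27 of 36 genes above 0 and 13 past the threshold, SHOC2 and SMC3 (1.92 and 1.40, log2) among them, and from PLCXD1 to KLHL34, with 34 of 39 and 13, passed at all 3 widths, while others were more mixed, such as DSCC1 to ST3GAL1 with 18 of 30 above 0, 6 higher and 3 lower; with 21 the largest medians of the first-named 2, 0.518 and 0.363, exceeded every shuffled order (at most 0.327), which argues against chance order, though at a width of 11 neither did and a run from NUDT21 to PSME3IP1 did, which holds the metallothionein cluster and so repeats the observation on that family. Shuffled orders treat neighbours as unrelated. Adjacent genes had a rank correlation of 0.0893 in the PRL-3 difference and of 0.223 on the within-group direction, so neighbours varied together within groups too. Exceeding the shuffled orders therefore does not tie the runs to PRL-3. With the within-group direction taken out the largest run median was 0.487, above the limit of 0.263. That removal rests on the same regression across genes, so it does not settle whether the direction plays a part. A gain of these segments in the PRL-3 cells may be a cause but cannot be told apart from other causes: 48 dimmer genes of the same segments had a median of 0.0048 against 0.259 for the brighter ones, near 0 although at the 96.2 percentile of 10000 random sets, the rule on how near they had to come to the brighter median was set after these values were seen, and dim genes can hide a shift.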
